A study of Mus musculus with 2 samples.

How the data were processed

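Gene expression was measured with Affymetrix mouse arrays on total RNA of C2C12 cells, a mouse myoblast cell line that forms multinucleated myotubes when serum is lowered. Per the labels' protocols, the cells were grown in medium with 10% fetal bovine serum and differentiated for 5 days in medium with 2% horse serum, RNA was extracted with Trizol, and biotin-labelled cRNA was prepared from 6 ug of total RNA. The sample labels name 1 array of cells with a hairpin against Lrrfip1 (shLrrfip1a) and 1 array of control cells (spelled shLCUI in the sample labels). There was 1 array per group, so no difference has a replicate check, and no p-value, standard error or SD between replicates can be given.

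The authors deposited 1 intensity value per probe set and array, on a linear scale. A probe set is the group of short array probes that reads 1 transcript region. The deposited intensities ran from a floor of 1 to 9165 on the shLrrfip1a array and to 9861 on the control array, with 12 and 23 probe sets at exactly 1. The medians were 53.5 and 51.4 and the upper quartiles 152 and 153, so the 2 arrays were on a nearly common level as deposited. The summary method, background correction, scaling and detection calls are not given in the sources used here. Without detection calls no probe set can be declared absent, and the precision is limited by the number of arrays.

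Of 45101 probe sets, 64 are Affymetrix controls. Through the platform annotation, 34958 probe sets had 1 gene symbol, 932 had several and 9211, including 51 of the controls, had none. Of those with 1 symbol, controls left out, 34741 matched the mouse gene table of assembly GRCm38.p6 by gene identifier, and none of their symbols differed from it. No genome build is named for the arrays, so no coordinates are given. Genes were not named from probe sets with several symbols.

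The analysis was run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. Values were taken as log2(intensity + 16), on the authors' scaling. Each difference is the shLrrfip1a value minus the control value on that scale, which understates the change of dim genes. A gene was represented by its probe set with the highest mean over both arrays, and it was kept when that mean lay above the median of all probe sets (an intensity of about 52.4), which left 11448 of 18193 genes. A fixed size of 2-fold, a log2 difference of 1, was used to count genes. For 23 gene lists, the median difference of the members above the filter was placed among 10000 random lists of the same size, drawn within 20 bins of mean level. A list was called apart at or below percentile 2.5 or at or above percentile 97.5. Lists of randomly drawn genes would give this for about 1.15 of 23 lists, and lists whose members vary together would give it more often. Such a percentile describes these 2 arrays and is not a test of the hairpin.

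The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names every Lrrfip1 probe set, the 12 genes with the largest difference in each direction, the 3 members of each list with the largest absolute difference, and 11 myogenic and cell cycle genes. For the 12 in each direction, the higher array had to lie above its 60th percentile, all probe sets of the gene above the filter had to differ in the same direction, and predicted genes were not named. The alternatives were median centring, quantile normalization, removal of a loess trend, no filter or a filter at the 75th percentile, the mean over a gene's probe sets, pseudocounts of 1 and 64, thresholds of 1.5-fold and 3-fold, and random lists not matched on level. Scaling to the bacterial spike-in controls and leaving out a list's most different member were added after the data were seen, as were 4 gene lists used in the closing section.

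The procedure was tested on simulated data with the real levels and the robust spread of the real differences. For 50 genes at each size among 11448, 58.0% of genes changed 2-fold and 100.0% of those changed 3-fold, 4-fold or 8-fold were called at least 2-fold in the right direction. Among 11248 unchanged genes 1 was called. Of 200 unchanged lists of 20 genes, 3.0% fell outside the central range, and all 200 lists shifted by 0.3 were called. The simulated noise was taken from the difference between these 2 arrays, so it does not stand for the spread between cultures. It was drawn independently for each probe set, so the simulated lists do not stand for genes that vary together. The noise was also drawn from a normal distribution with the robust spread, which leaves out the tails of the real differences. The 1 call among unchanged genes therefore does not estimate how many of the real calls are noise.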

Results

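The series compared the transcriptomes of differentiated C2C12 cells that carried a hairpin against Lrrfip1 (shLrrfip1a) with those of cells that carried a control hairpin, to list the genes that differed between them. Lrrfip1 encodes a nucleic acid-binding protein that has been described as a transcriptional repressor and as an interactor of the actin regulator Flii. Each group was represented by 1 array of 45101 probe sets, read after 5 days of differentiation. The 2 arrays had a Pearson correlation of 0.99 over all non-control probe sets, which are not independent replicates. Of 11448 genes above the median level, 92.6% differed by less than 0.5 on the log2 scale. All values below are deposited intensities or log2 differences, shLrrfip1a minus control, and a difference is called at least 2-fold by size alone because no replicate exists.

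Lrrfip1 itself was lower in the shLrrfip1a array on all 3 of its probe sets. The intensities were 375 against 531, 108 against 160, and 292 against 469 in the control. The mean log2 difference over the 3 probe sets was -0.55 ± 0.09 (SD over probe sets of the same RNA, not over replicates), and the unadjusted intensities were 62.2% to 70.6% of the control values. Lrrfip1 thus stayed under the 2-fold size, and 4.07% of genes had a lower difference. Lrrfip2, a paralog, differed by -0.46 on its brighter probe set (216 against 302) and by 0.14 on the other, and Flii differed by 0.07. Where on the transcript the hairpin and the probe sets lie was not analysed here. Scaling the arrays to the bacterial spike-in controls moved the mean Lrrfip1 difference to -0.40.

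In all, 76 genes were at least 2-fold higher and 79 at least 2-fold lower in the shLrrfip1a array, 1.35% of the genes measured. The largest positive difference was that of Dcn, which encodes the small leucine-rich proteoglycan decorin, at 3497 against 260 (log2 difference 3.67). It was followed by Omd, a related proteoglycan gene (710 against 63.3, 3.19), and Car3, a carbonic anhydrase of muscle and fat (3372 against 368, 3.14, with 3.28 on its other probe set above the filter). Other secreted or matrix proteins were among the 12 largest: Igfbp3, which binds insulin-like growth factors (613 against 97.9, 2.47), the matricellular Ccn3 (2447 against 489, 2.29), the fibulin Fbln7 (729 against 142, 2.24) and the collectin Colec10 (168 against 16.2, 2.51). The remaining ones were Klhl13 (2.96), Lyz1 (2.91), Ranbp3l (2.43), the alcohol dehydrogenase Adh1 (631 against 108, 2.38) and the noradrenaline transporter Slc6a2 (777 against 143, 2.32). The Lyz1 value came from probe sets that can bind related transcripts, a further Lyz1 probe set was dim on both arrays (14.7 and 17.1), and the near-identical Lyz2 differed by 1.48. Klhl13 and Slc6a2 differed less on their other probe sets above the filter, by 1.09 for Klhl13 and by 0.61 and 0.59 for Slc6a2. Colec10, Lyz1 (21.1) and Klhl13 (34.7) lay below the control array's median of 51.4 in the control, so the size of their difference depends on the pseudocount. With pseudocounts of 1 and 64, Colec10 differed by 3.30 and 1.53, Lyz1 by 3.57 and 1.94, and Klhl13 by 3.41 and 2.17.

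The largest negative difference was that of Sulf1, an extracellular enzyme that removes sulfate from heparan sulfate, at 13.1 against 584 (log2 difference -4.37) and -3.07 on its other probe set above the filter. Ms4a4d, of a family of membrane-spanning proteins, read 30.5 against 556 (-3.62). The membrane-bound carbonic anhydrases Car9 (131 against 823, -2.52) and Car12 (35.1 against 267, -2.47) came next, then Prg4, which encodes lubricin (59.9 against 376, -2.37). The acid phosphatase Acpp (-2.27), the cholesterol hydroxylase Ch25h (-2.20), the pyrimidine-degrading Dpyd (-2.10), Fibin (-2.05), Ccbe1 (81.1 against 373), the G-protein subunit Gng11 (98.1 against 439) and Plac8 (-1.89) completed the 12. Sulf1, Ms4a4d, Car12, Acpp, Ch25h, Dpyd, Fibin and Plac8 lay below the array's median of 53.5 in shLrrfip1a, so the size of their difference depends on the pseudocount.

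**Figure D1:**
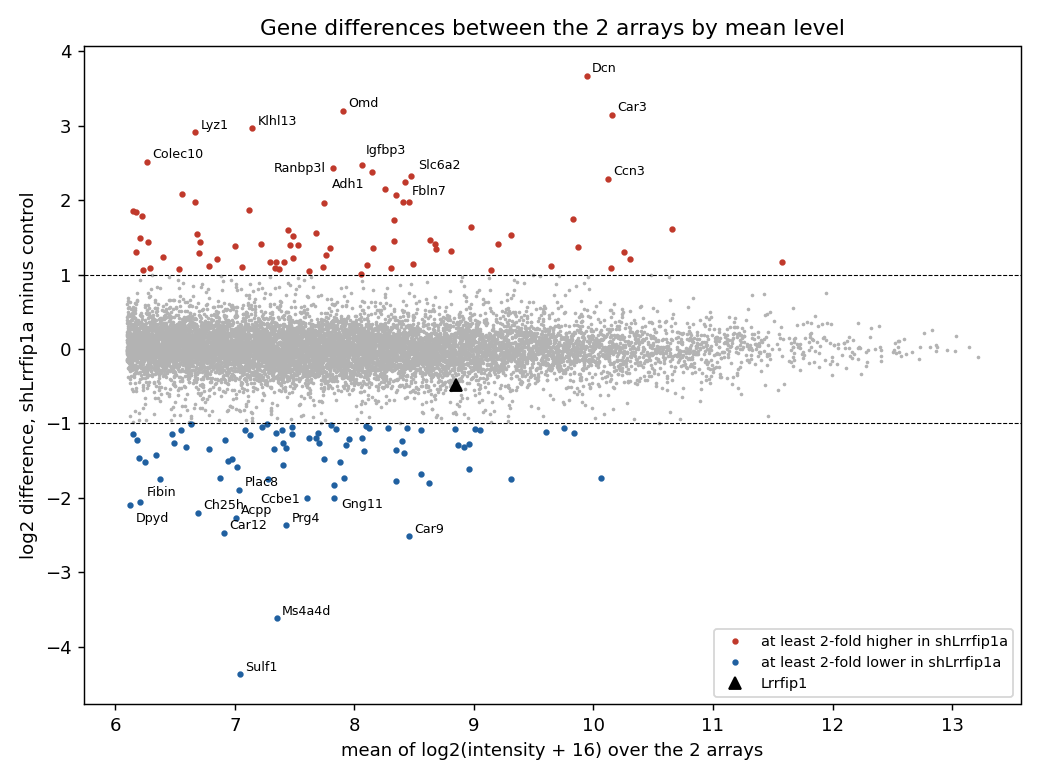
Each point is 1 of 11448 genes, with its mean log2(intensity + 16) over the 2 arrays on the x axis and its log2 difference, shLrrfip1a minus control, on the y axis. The dashed lines mark 2-fold; 76 genes lie on or above the upper line and 79 on or below the lower one, and Lrrfip1 (triangle) lies at -0.48 on its brightest probe set.

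Of 127 genes in the 7 muscle lists, 3 reached 2-fold, namely Myh1, Trdn and Itga6. That is 2.36%, against 1.35% of all 11448 genes, so the muscle lists were not shown to be more level than other genes. Outside the lists, and chosen after their values were seen, the muscle genes Csrp3 (282 against 712, -1.29), Smpx (320 against 124, 1.26) and Synm (288 against 84.5, 1.60) were past 2-fold. None of 12 measured myogenic regulators reached 2-fold, and their median difference was 0.01 (percentile 54.5 of matched random lists). The largest differences among them were those of Myf5, an early determination factor (82.8 against 159, -0.83), Myod1 (894 against 602, 0.56) and Myog, the factor of terminal differentiation (2005 against 2612, -0.38). Myf6 (27.6 and 32.0) and Mef2c (47.1 and 45.2) lay below the level filter on both arrays.

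Of 36 sarcomere genes, 35 stayed under 2-fold and the list median was -0.06 (percentile 5.91). The adult fast myosin heavy chain Myh1 read 1908 against 765 (1.30), although its probe set can bind related myosins. The embryonic myosin Myh3 read 1294 against 1256 (0.04) and skeletal actin Acta1 5220 against 5586 (-0.10). The fast troponin Tnni2 (652 against 1081, -0.72) and the embryonic light chain Myl4 (1482 against 2406, -0.69) were the lowest 2 members. With quantile normalization or the stricter level filter the sarcomere median came to -0.09 and -0.10 and was called apart (percentiles 1.27 and 1.18). Its members were spread with an SD of 0.41, at percentile 93.6 of matched random lists.

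Among 19 genes of excitation-contraction coupling, Trdn, which encodes the junctional protein triadin, was the 1 member past 2-fold (178 against 30.0, 2.07). It was dim in the control, and its difference was 2.53 with a pseudocount of 1 and 1.36 with 64. Cacnb1 (-0.74 on its chosen probe set, 0.11 and 0.23 on others) and Ryr3 (0.51) followed, and the list median was 0.02 (percentile 61.9), with an SD over members of 0.56, at percentile 97.8. Of 26 fusion and adhesion genes the laminin receptor subunit Itga6 was the 1 past 2-fold (148 against 361, -1.20). In the same list Cdon (-0.62) and Adam12 (-0.58) were the next largest, the median was -0.06 (percentile 10.1), and the fusion protein gene Mymk read 734 against 787 (-0.10). No member reached 2-fold among 9 neuromuscular junction genes (median 0.07, percentile 80.2), 15 muscle energy genes (0.08, 85.8) or 10 dystrophin complex genes (-0.09, 15.3). Their largest differences were -0.76 for Erbb3, 0.37 for Lrp4 and -0.13 for Chrnd, then -0.68 for the hexokinase Hk2, -0.57 for the glycogen synthase Gys1 and 0.44 for Pfkm, and lastly -0.29 for Sspn, -0.20 for Bves and -0.17 for Dtna. The creatine kinase Ckm read 422 against 321 (0.38). With the stricter level filter, which left 10 energy genes, that list's median was -0.17 and lay at percentile 1.86.

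**Figure D2:**
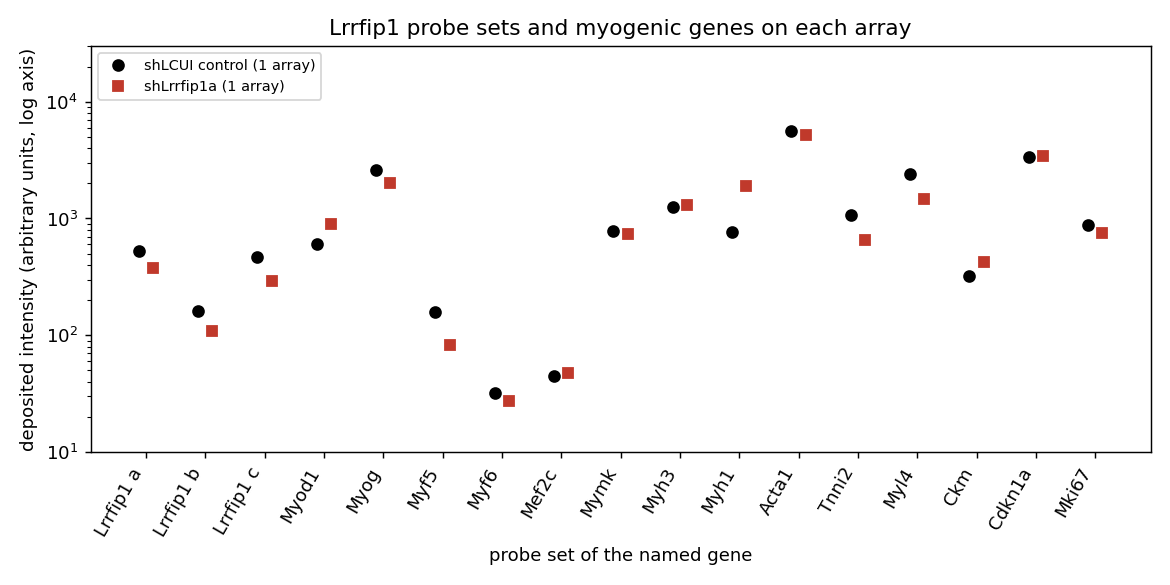
Deposited intensity on a log axis for the 3 Lrrfip1 probe sets (a, b and c) and 14 myogenic and cell cycle genes, 1 array per group, so there are no error bars. All 3 Lrrfip1 probe sets are lower in shLrrfip1a, whereas Myh3, Acta1 and Cdkn1a are close to level and Myh1 is higher.

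Cell cycle genes had a median of -0.08 over 40 genes, at percentile 3.70 and so inside the central range; the percentile was 2.18 against random lists not matched on level, and 24.5 (median -0.03) with the mean over probe sets. The cyclin Ccnd2 was the 1 member past 2-fold (304 against 756, -1.27, lower on all 6 of its probe sets above the filter), while Ccnd1 was higher (1339 against 955, 0.48). Cenpf differed by -0.44, and the proliferation marker Mki67 read 749 against 881 (-0.23). Of 13 genes of cell cycle exit, the inhibitor Cdkn1c was past 2-fold (146 against 50.4, 1.29; 0.88 with a pseudocount of 64), Gadd45a and Gadd45g differed by -0.68 and -0.46, and Cdkn1a was level (3396 against 3335, 0.03). The list median was -0.05 (percentile 24.6), but -0.18 with the mean over probe sets, where the list was called apart (percentile 0.75), and -0.14 with the stricter level filter (percentile 4.30).

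Matrix genes used as fibroblast markers differed in both directions. Of 34, 3 were at least 2-fold higher, namely Dcn, Fbln1 (571 against 160, 1.73) and the gelatinase Mmp2 (4564 against 2017, 1.17). The proteoglycan gene Vcan was at least 2-fold lower (-1.13, chosen after its value was seen), and the list median was 0.06 (percentile 87.7). Of 25 genes of the actin cytoskeleton and smooth muscle none reached 2-fold (median 0.01, percentile 56.5), with Actg2 at -0.76, Cnn2 at 0.52 and Ankrd1 at -0.46. Markers of other lineages were mostly dim, with 4 of 11 osteoblast and chondrocyte genes and 5 of 12 adipocyte genes above the filter. The 4 osteoblast and chondrocyte genes were all higher (median 0.37, percentile 99.6), led by Omd, with Phex at 0.43 and Alpl at 0.32, but without Omd the other 3 lay at percentile 96.0, and without a filter 11 genes at 97.3. The 5 adipocyte genes had a median of 0.15 (percentile 89.2), with Lpl at 0.62, Dgat2 at -0.23 and Cebpa at 0.19.

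Among signalling lists, the insulin-like growth factor axis was called apart with a median of -0.24 over 11 genes (percentile 0.26), while its mean was 0.19. Its largest members were the higher ones, Igfbp3, Igf1 (1163 against 581, 0.98) and Igf2 (635 against 329, 0.92), and 7 members were lower. The call was lost with the stricter filter (percentile 4.39) and with the mean over probe sets (3.06). BMP and TGF-beta targets had a median of 0.15 over 17 genes (percentile 98.6), led by the differentiation inhibitor Id3 (516 against 178, 1.46), Fst, an antagonist of activin and myostatin (1375 against 695, 0.97), and the BMP antagonist Grem1 (283 against 547, -0.91). Without Id3 that list lay at percentile 88.3, with the mean over probe sets at 75.4 and without a filter at 72.6. NF-kB and inflammatory genes had a median of 0.15 over 19 genes (percentile 99.3), yet 3 members were at least 2-fold lower and 1 was higher. Il33 read 160 against 587 (-1.78), Il6 93.5 against 247 (-1.26; -0.98 with a pseudocount of 64) and Cxcl5, a neutrophil chemokine, 1653 against 482 (1.74). The stricter filter left 13 of these genes at percentile 96.8.

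The other signalling lists were not called apart. Wnt genes had a median of -0.02 over 20 genes (percentile 32.0), which turned to 0.06 over the 9 left by the stricter filter (77.3), and the secreted antagonists Sfrp1 and Sfrp2 differed in opposite directions, by -1.75 (lower on all 4 probe sets) and 1.61 (2804 against 907), with Wnt10a at -1.58. Notch genes had a median of 0.14 over 13 genes (percentile 94.5), with Lfng at 0.92, Notch3 at -0.74 (-0.38 with the mean over probe sets) and Notch1 at 0.44, but the 8 left by the stricter filter had a median of -0.03 (36.9). No interferon response gene of 30 reached 2-fold (median 0.05, percentile 87.4), and the largest differences were those of Ccl5 (545 against 1029, -0.90), the RNA sensor Ifih1 (-0.82) and the immunoproteasome subunit Psmb8 (-0.76). That list was called apart with the mean over probe sets (0.09, percentile 98.2), while its median was -0.01 without a filter (41.6). Endoplasmic reticulum stress and p53 targets had a median of -0.11 over 20 genes (percentile 2.90), with Fas at -0.74, Trp53inp1 at 0.58 and Mdm2 at 0.57, and the list was called apart with quantile or loess scaling (2.47 and 1.92). Of 4 listed genes reported to be repressed by LRRFIP1, 3 lay above the filter and Slc1a2 did not. Pdgfa differed by -0.31 (-0.59 on its other probe set), Tnf by 0.17 and Egfr by -0.01 (median -0.01, percentile 40.6). Tnf was close to the filter level (66.4 against 57.3). The list of Lrrfip1 and its family, at percentile 0.88, holds the targeted gene itself, so its call is not independent of the knockdown, and it lay at 15.3 with the mean over probe sets. Reference genes had a median of -0.01 over 14 genes (percentile 37.3), with Polr2a at 0.46, Pgk1 at -0.35 and Actb at 0.22.

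**Figure D3:**
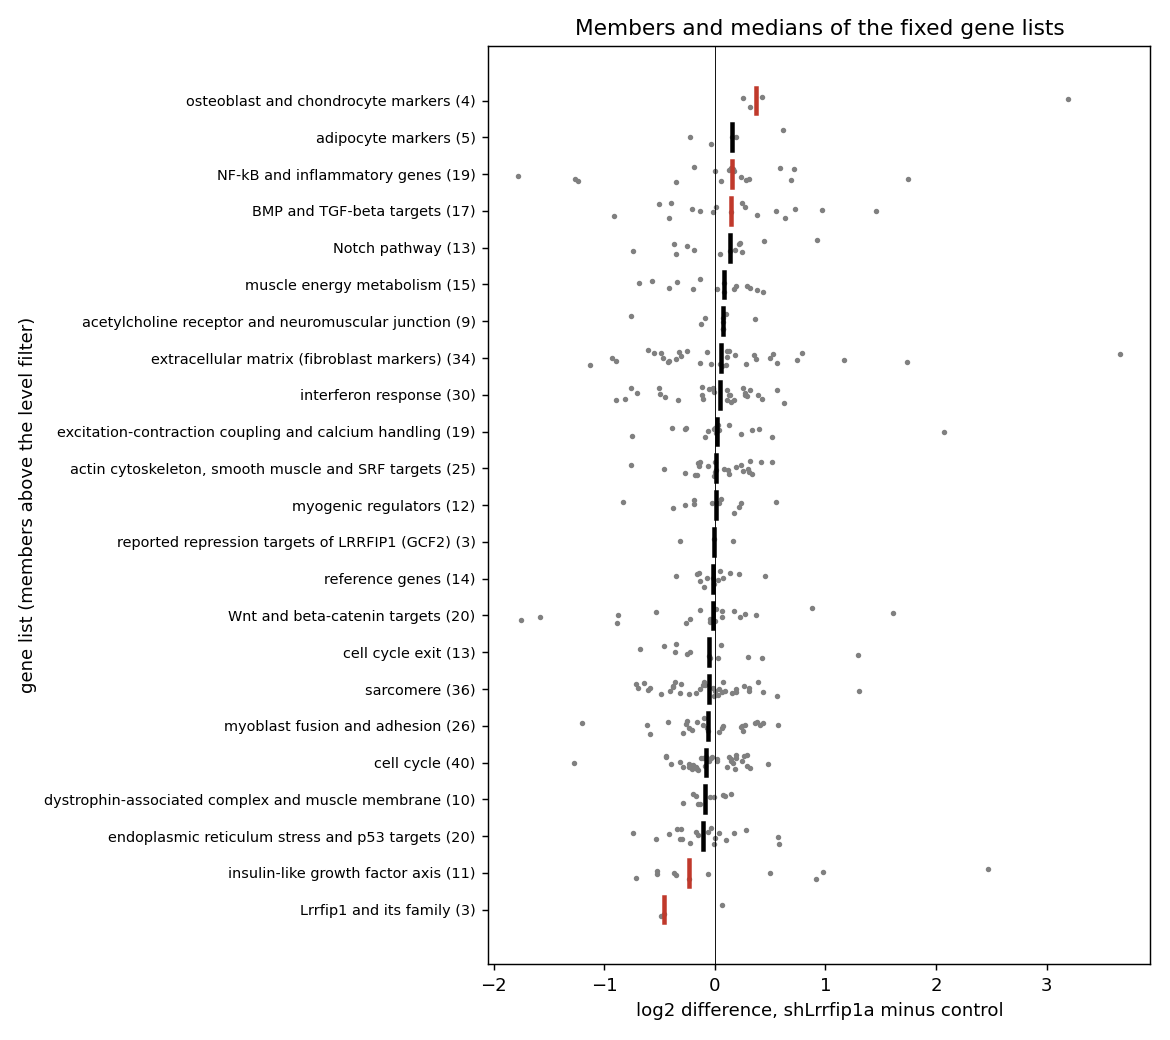
Each grey point is 1 member of a fixed gene list, with its log2 difference, shLrrfip1a minus control, on the x axis and the number of members above the level filter in brackets. Vertical bars are list medians, red for the 5 of 23 lists called apart; the muscle lists have medians between -0.09 and 0.08.

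Of 23 lists 5 were called apart, 3 higher and 2 lower, where lists of randomly drawn genes would give 1.15. The 5 include the list that holds Lrrfip1 itself. Members that vary together would raise the number given by chance, so an excess over chance was not shown. Median and mean differed in sign for the myogenic regulators (0.01 and -0.05), neuromuscular junction (0.07 and -0.02), muscle energy (0.08 and -0.02), interferon response (0.05 and -0.04) and insulin-like growth factor lists. Probe sets of 1 gene served as the within-array check. Among 54 genes past 2-fold with several probe sets above the filter, all probe sets differed in the same direction in 52, or 96.3% (Wilson 95% interval 87.5% to 99.0%), against 60.3% of all 4853 such genes and 37.3% with independent signs. The 54 genes were chosen by size on 1 of these probe sets, and all probe sets of a gene read the same RNA sample. The agreement thus bears on noise of single probe sets, not on differences between cultures. The log2 ratio of the 3-prime to the 5-prime control probe set was -0.04 and 0.00 for Gapdh in shLrrfip1a and control, and 0.52 and 0.74 for beta-actin. On the bacterial and phage spike-in controls, 38 of 42 probe sets were lower in the shLrrfip1a array (median -0.16). All 24 B. subtilis probe sets were lower (median -0.20). Of the 18 E. coli and P1 probe sets, 14 were lower and 4 higher (median -0.06), so the kinds of control differed in the size of the shift. Scaling the arrays to these controls added 0.15 to the difference of every gene, which turned the 76 higher and 79 lower genes into 116 and 54. The 9 list medians that lay closer than this below 0 became positive by that uniform shift, and no list percentile moved. Scaling to the B. subtilis controls alone, or to the E. coli and P1 controls alone, was not tested.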

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

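Probe sets that carry no single gene symbol were left out of the gene comparison and were examined as a separate signal. Of 3042 such probe sets above the level filter, 13 were at least 2-fold higher and 16 at least 2-fold lower in the shLrrfip1a array. Of the 13, 3 are shared by the genes of the Ugt1a cluster, which encode enzymes that attach glucuronic acid to drugs and bilirubin. They read 1944 against 823, 570 against 221 and 448 against 170, with a median log2 difference of 1.31. Which Ugt1a gene gave the signal was not resolved by these probe sets.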

How the results depend on the processing

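With 1 array per group no library can be left out, and no spread between cultures is known. No paired analysis was possible because each group has 1 sample. The higher and lower counts (76 and 79) came to 48 and 46 with the 75th percentile filter, 268 and 282 at 1.5-fold, and 28 and 23 at 3-fold. The higher and lower counts were 52 and 44 with a pseudocount of 64, and 94 and 103 with a pseudocount of 1. They were 116 and 54 with spike-in scaling, which also moved the mean Lrrfip1 difference from -0.55 to -0.40. Under the 3 planned scalings every one of the 79 lower genes and at least 75 of the 76 higher ones were called again. The share of genes with agreeing probe sets was 70.5% with the 75th percentile filter, against 60.3%. List medians called apart only under an alternative were those of sarcomere genes (-0.089 with quantile scaling, -0.097 with the 75th percentile filter), stress and p53 targets (-0.12 with quantile, -0.13 with loess), cell cycle exit (-0.18, mean over probe sets), interferon response (0.095, mean over probe sets) and cell cycle (-0.082, unmatched random lists). Calls lost were BMP and TGF-beta targets (0.045 without a filter, 0.048 with the mean over probe sets, 0.079 without Id3), osteoblast and chondrocyte markers (0.18 without a filter, 0.32 without Omd), NF-kB genes (0.13, 75th percentile filter), the insulin-like growth factor axis (-0.15 with that filter and with the mean over probe sets) and the Lrrfip1 family (-0.16, mean over probe sets). The energy list turned from 0.08 to -0.17 with the 75th percentile filter, which left 10 of its 15 genes. Without spike-in scaling, 13 list values from 8 lists turned in sign; beside energy these were Notch (-0.035) and Wnt (0.062) with that filter, interferon (-0.011, no filter) and, from medians near 0, myogenic regulators, excitation-contraction coupling, actin and repression targets. The cause of these moves was not tested beyond the smaller number of genes under the stricter filter. The other 192 list values under alternatives kept their side of the threshold. Those under median centring could not do otherwise, because it shifts every gene by the same amount. Of 839 values of named genes under alternatives 53 moved, in 32 genes, 30 with a pseudocount of 64, 14 with 1 and 9 with the mean over probe sets; Cdkn1c (0.88) and Il6 (-0.98) came under 2-fold with 64. No named gene past 2-fold changed sign. The signal of dim probe sets, with no detection calls, limits the size of the largest differences.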

Other observations

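The gene lists in this part were written after the largest differences had been seen. The tests on matrix genes, on sarcomere genes and on the 2 cultures were also chosen after the result was seen, whereas the members of the 4 added lists had not been looked at when their tests were set. Spike-in scaling was not run on the 4 added lists. Its shift of 0.15 in every gene would raise their medians and leave their percentiles as they are.

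Most of the genes looked at here that are known to respond to low oxygen were lower in the shLrrfip1a array. Beside Car9 and Car12, the prolyl hydroxylase Egln3 (332 against 1146, -1.74), the mitophagy receptor Bnip3 (570 against 1929, -1.73), Ier3 (-1.68), Mgarp (-1.48) and the placental growth factor Pgf (-1.05) were noticed among the genes at least 2-fold lower. Of 29 further hypoxia-responsive genes, 25 were lower and 4 higher, with Ero1a (337 against 732, -1.08), Tmem45a (-0.92), P4ha2 (-0.88), Adm (-0.84), Higd1a (-0.81), Ndrg1 (758 against 1323, -0.79) and Vegfa (278 against 475, -0.74) among them. A list of genes of glycolysis and of mitochondrial pyruvate entry had 8 members lower and 5 higher, with a median of -0.24 over all 13 (percentile 0.19). It shared 4 members with the hypoxia list; the other 9, of both kinds, had a median of -0.19 (percentile 1.61), from Pfkp (-0.85) to the pyruvate carrier Mpc1 (0.27). The list left out glycolytic genes already in the energy list, such as Pfkm (0.44), Pgam2 (0.29) and Aldoa (0.02). A set of 19 glycolytic enzymes and lactate dehydrogenases above the filter was formed after many of their values were seen. Of these, 13 were lower and 6 higher (median -0.23, percentile 0.01). The set was not complete, as it held no value for Gapdh, Gpi1 or Eno1.

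Single genes at least 2-fold higher, picked after their values were seen, encode enzymes that act on xenobiotics or aldehydes, namely Ces2g (630 against 130, 2.15), Cyp2f2 (1.78), Aldh3a1 (1.54), Fmo1 (1061 against 357, 1.53), Gstm1 (638 against 242, 1.35, higher on all 4 probe sets) and Fmo2 (1.11). Further genes past 2-fold that encode matrix or adhesion proteins, picked after their values were seen and not tested as a group, were Cdh11 (196 against 719, -1.79), Dpt (-1.73), Col5a3 (-1.40) and Col11a1 (-1.19) on the lower side and Col27a1 (1.56) and Cilp (941 against 346, 1.40) on the higher side.

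The first pattern weighed is the lower level of hypoxia-responsive genes. The 29 genes not seen before had a median of -0.31, and none of the 10000 matched random lists was as low (percentile 0.0), which is consistent with a lower level of the group in this sample. Without 10 members singled out once their values were known, 17 of the other 19 were lower, with a median of -0.30 (percentile 0.0). Those 10 included the higher genes Pfkfb4 (0.22) and Aldoc (0.02) along with lower ones. Their removal thus did not work only against the pattern and adds little support to it. The median was still -0.33 with the loess trend removed, so a trend with level did not account for it. The random lists were already matched on level, so the percentile after loess (0.0) could hardly have moved and adds no support. Among the 21 genes above the 75th percentile of level the median was -0.35 (percentile 0.0), which argues against noise of dim probe sets. With 1 culture per hairpin, a difference between the cultures, such as cell density or medium depth, cannot be told apart from an effect of the hairpin.

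The second pattern is the spread of matrix genes in both directions. The SD of the differences over the 34 listed genes was 0.86, wider than in every matched random list (0.0% as wide), and 0.60 without Dcn (percentile 98.9), while their median lay at percentile 87.7. The spread of 4 other lists was also wide, at percentile 99.7 for the insulin-like growth factor axis, 98.6 for NF-kB, 98.5 for Wnt and 97.8 for excitation-contraction coupling genes. If all these markers were higher in fibroblast-like cells, a different share of such cells would move them the same way. Of the 34 genes 18 were higher and 16 lower, from Dcn (3.67) to Vcan (-1.13). Whether the markers share a direction in these cells was not measured, so a different share of fibroblast-like cells stays open. In the 23 members with several probe sets above the filter, which leave out Dcn, the difference of the chosen probe set went with that of the others (Spearman correlation 0.926, 95% bootstrap interval 0.750 to 0.991), which argues against noise of dim probe sets in these members. A difference between the cell populations that carry each hairpin, or an effect of the hairpin, stays open and was not tested.

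The third pattern is that 1 of 36 sarcomere genes was past 2-fold, which does not make them level, since their SD lay at percentile 93.6 and their median at 5.91. If bright probe sets were compressed, the dimmer members could show a larger drop. The 18 dimmer members had a median of 0.016 (SD 0.47 over genes) and the 18 brighter ones -0.14. The dimmer members thus showed no larger drop, the direction set to count against compression, but the spread between members leaves compression open.

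As hypotheses, 2 further groups were tested on members not seen before. The 23 xenobiotic and aldehyde metabolism genes, 0 of them past 2-fold, had a median of 0.11, at percentile 96.6, short of the threshold, with Akr1c14 (0.82), Gsta4 (0.82) and Gstt3 (0.58) the highest and Akr1b8 (-0.62) the lowest; the percentile was 98.2 with quantile and 97.7 with loess scaling and 99.9 without a filter, but 81.0 (median 0.053, 16 genes) with the 75th percentile filter, so the group difference stays open. The imprinted genes Mest (1.39), Cdkn1c (1.29), Peg3 (1162 against 530, 1.11) and Igf2 (0.92) were higher, but 15 other imprinted genes had a median of 0.04, at percentile 64.3, and without a filter 28 had a median of 0.10, at percentile 94.9, so a rise of imprinted genes as a group was not shown and stays open. The bound set beforehand for excluding such a rise, percentile 75, was met by the main value, but it was judged too weak after the alternatives were seen, because the value without a filter lies above it.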
